A study of Mus musculus with 4 samples.

How the data were processed

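Gene expression was measured on 4 single-channel mouse arrays, each hybridised with total RNA of 1 sample of 32D MPL-HA cells. The 4 groups were Calr del52 cells and Jak2 V617F cells, each mock treated or treated with murine interferon-alpha (100 IU, with no volume stated) for 4 h. The labels' protocols give growth in RPMI with fetal calf serum and interleukin-3, RNA isolation with Trizol and chloroform, and biotin-labelled cDNA made from 300 ng of RNA with the WT Plus kit. Each group held 1 array. The labels do not say how many clones or cultures stand behind a sample.

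The deposited values are log2 probe set signals. The submitters' processing notes name Affymetrix Expression Console, RMA and Transcriptome Analysis Console, with no version, role or order. RMA corrects background, normalizes between arrays by quantiles and summarises the probes of a probe set on the log2 scale. The deposited arrays did not have identical distributions: their medians were 7.44 (Calr del52, mock), 7.42 (Calr del52, interferon), 7.49 (Jak2 V617F, mock) and 7.45 (Jak2 V617F, interferon). The genome build and annotation release are not given in the sources used here, so no coordinates are printed.

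The table held 22206 probe sets. A dated platform annotation named 1 gene for 19572 of them, several genes for 0, and none for 2634, which are counted but not named. All 19572 named probe sets matched a RefSeq gene table of assembly GRCm38.p6 by gene identifier, and 0 symbols changed. They stood for 19505 genes, of which 55 had several probe sets, and the probe set with the highest mean over the 4 arrays then stood for the gene. No probe set was named Stat1 or Mpl, so neither gene is reported. Arrays of this kind do not fully separate near-identical paralogs (the Ifit, Gbp, Ifi2xx, Phf11, Apol9 and Tgtp families), and values of single members of these families are uncertain for that reason.

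With 1 array per group, no comparison of single arrays has a replicate check, and none has a p-value. A probe set counted as higher or lower when its log2 difference was at least 1 (2-fold) and the brighter of the arrays compared was at or above a floor of 7.45, the median of all values. The floor is not a detection limit, and a difference whose dimmer value lies below it is uncertain in size. In the text, "rose" and "fell" are used for genes that passed this rule. The comparisons were interferon against mock in each line, the difference between these responses (Jak2 V617F minus Calr del52), and Jak2 V617F against Calr del52 in mock-treated and in interferon-treated cells. The difference in response equals the line difference after interferon minus the line difference in mock-treated cells, so the last 3 comparisons are not independent.

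An additive model with line and treatment was fitted with limma 3.58.1 in R 4.3.3 to the 11745 probe sets at or above the floor on at least 1 array, with empirical Bayes variances and Benjamini-Hochberg adjustment at 0.05. It leaves 1 residual degree of freedom, which is the disagreement between the lines in their response, and the prior contributed 2.43 degrees of freedom. Its p-values therefore say whether an effect was alike in both lines relative to that disagreement, and do not cover the spread between cultures or clones. Different amounts of response in the lines add to the residual, so a gene that responded in both lines can miss a call in this model.

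Before the data were examined, 20 gene lists holding 589 genes were written down, and 506 of these genes were measured. For each list the members that passed the size rule were counted, and the median log2 difference was ranked among 10000 random lists of the same size matched on mean expression in 20 bins. These ranks describe the arrays and are not p-values. Genes named in the text followed a rule fixed at the same time. It took Jak2, Calr and Mpl, 11 interferon pathway genes, the 10 largest differences in each direction per comparison (without predicted genes), up to 4 members per list, and the 10 smallest adjusted p per direction in limma. Genes named outside the rule are marked as chosen after their values were seen. Tables were handled in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

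The limma step was tested on simulated data of the same 11745 probe sets, with 50 changed per effect size. For the interferon effect it called 0 of 50 at a log2 size of 1, 29 at 2, 37 at 3 and 46 at 4, with 3 false calls. For the line effect it called 0, 25, 41 and 42 of 50 at these sizes, with 0 false calls. Each simulated interferon effect was the same in both lines, and each line effect the same in both treatments. These rates therefore do not carry over to genes whose response differed between the lines. The noise was drawn from the variance prior that limma estimated on the real arrays. The false calls are thus those of data that meet the assumptions of the model. The list ranking was tested on simulated lists of 25 genes for the line difference in mock-treated cells. All 100 lists shifted by 0.5 lay outside the central 95% of random lists, as did 4 of 100 lists left unshifted. The simulated lists were genes drawn at random, and the shift was added to every member. They therefore do not show how often a real list, whose genes may vary together, lies outside that range.

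Alternatives covered the floor (none, or the 75th percentile), the size rule (1.5-fold or 4-fold), the normalization (quantile, median centring or cyclic loess on the deposited values), limma without the block, with a variance trend and without each array in turn, list medians from mean probe sets, and list members above the floor. No sequence depth applies to arrays, and the number of arrays limits the precision. As a measure of noise, the 10461 probe sets below the floor on all 4 arrays had a central 95% of differences from -0.54 to 0.50 for the response of Calr del52 cells and from -0.59 to 0.46 for that of Jak2 V617F cells. The same range ran from -0.74 to 0.63 for the difference in response, from -0.42 to 0.58 between lines in mock-treated cells, and from -0.48 to 0.54 between lines after interferon.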

Results

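Transcript levels were measured on 4 mouse arrays in 32D MPL-HA cells. 32D is an interleukin-3-dependent myeloid progenitor line, which the submitters' source field describes as myoblast-like, and MPL is the thrombopoietin receptor. One line carried Calr del52, a frameshifting deletion in calreticulin, a chaperone of the endoplasmic reticulum. The other carried Jak2 V617F, an activating substitution in the kinase that signals for cytokine receptors. Both mutations are known from myeloproliferative neoplasms. Each line was mock treated or treated for 4 h with 100 IU murine interferon-alpha, which signals through JAK1, TYK2, STAT1, STAT2 and IRF9. The question is whether cells with JAK2 V617F and cells with CALR mutations differ in their molecular response to interferon-alpha, and the series title names the response with JAK2 V617F as the increased one. There was 1 array per group and thus no replicates, so differences between single arrays have no test. All values are log2 signals, which ran from 3.34 to 14.06. Over all probe sets, arrays of the same treatment correlated more closely (r = 0.9933 for mock and 0.9947 for interferon) than arrays of the same line (0.9847 for Calr del52 and 0.9875 for Jak2 V617F). These correlations run across probe sets, which are not independent replicates.

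The mutated genes were read first, as a check of the labels. Jak2 was at 10.74 in mock-treated Calr del52 cells and at 13.21 in mock-treated Jak2 V617F cells, a difference of 2.47 or 5.54-fold. After interferon it was at 11.84 and 13.15. The higher Jak2 signal in both Jak2 V617F samples goes the way the labels would have it if the mutant was introduced on a construct that these probes detect, which the sources used here do not state. Calr was at 13.15 and 13.11 in Calr del52 cells and at 13.18 and 13.41 in Jak2 V617F cells, differences below the 2-fold rule. A small deletion need not change the signal of the whole probe set, so the Calr values check nothing about that label.

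In Calr del52 cells, interferon raised 305 probe sets at least 2-fold and lowered 14. Of those that rose, 131 rose at least 4-fold and 43 at least 16-fold, while 0 fell 4-fold. The largest named increases were in Gbp2, an interferon-induced GTPase, and Ifit1bl1 (both 6.64). Tnfsf10, which encodes the death ligand TRAIL, rose by 6.49, the antiviral GTPases Mx1 and Mx2 by 6.18 and 5.72, and the RNA-binding Ifit1 and Ifit3 by 6.11 and 5.63. The immunity-related GTPases Igtp and Iigp1 rose by 5.69 and 5.63, and Slfn5 by 5.58. All 10 started below the floor in mock-treated cells, so the sizes and order of these increases are uncertain. With values below the floor set to the floor, Gbp2 rose by 4.89, Ifit1bl1 by 5.38 and Ifit1 by 5.79. Of the 59 measured classical interferon-stimulated genes, 55 rose and 0 fell, with a median of 3.22, above all 10000 random lists. Of 28 measured genes driven through GAS sites or IRF1, 18 rose, with a median of 2.11. Gbp3, at 5.43, was among the largest.

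Several other fixed groups held members that rose in Calr del52 cells. Among 25 class I antigen presentation genes, 11 rose, led by the immunoproteasome subunit Psmb10 (2.45), H2-T22 (2.27), Tapbpl (2.10) and the peptide transporter Tap1 (1.89). Among 25 cell death genes 5 rose, including Tnfsf10, Daxx (2.78) and the inflammatory caspases Casp4 (2.48) and Casp1 (1.95). The 29 components of interferon and cytokine signalling had 5 members that rose: the feedback protease Usp18 (4.50), Stat2 (3.02), the feedback inhibitor Socs1 (2.09), Irf9 (1.45) and Jak2 itself (1.10). Ifnar1 (-0.09), Ifnar2 (0.10), Jak1 (0.17) and Tyk2 (-0.13) did not pass. Irf7 rose by 5.42 and Irf1 by 2.07. Of 29 NF-kB and inflammation genes 2 rose, the double-stranded RNA sensor Tlr3 (5.55) and the cytokine Il15 (2.28). Of 17 erythroid genes 2 rose, Rhag (1.75) and Lmo2 (1.04), with a list median of 0.05. Among 27 STAT5 targets, Socs1 and Osm (1.20) rose. The 9 named genes that fell were Mfng (-1.28) and Lfng (-1.22), which encode fucose-extending glycosyltransferases that modify Notch, Galnt6 (-1.13), the RNase gene Zc3h12a (-1.10), the urokinase receptor gene Plaur (-1.10), Itgae (-1.08), Ptgir (-1.05), Got1 (-1.05) and the clock repressor gene Nr1d1 (-1.04). With values below the floor set to the floor, Itgae (-0.15) and Nr1d1 (-0.61) lost the call. Under cyclic loess normalization Ptgir (-0.98), Got1 (-0.99) and Nr1d1 (-0.98) missed the 2-fold rule.

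In Jak2 V617F cells, interferon raised 281 probe sets and lowered 16. Of these, 94 rose at least 4-fold and 19 at least 16-fold. The largest named increases were Ifit1bl1 (5.75), Tnfsf10 (5.66), Ifit1bl2 (5.63), Ifi211 (5.58), Mx1 (5.55), Tlr3 (5.46), Ifit3 (5.17), Ifit3b (5.15), the antiviral radical enzyme gene Rsad2 (5.06) and Ifi44l (4.57). All 10 started below the floor, so this order is uncertain too. Of the classical interferon genes 52 of 59 rose, with a median of 2.40, and of the GAS and IRF1 targets 17 of 28, with a median of 1.38. The latter were led by the chemokine Cxcl10 (4.07), Gbp3 (4.02), Gbp9 (3.49) and Gbp2 (3.07). Class I presentation had 9 of 25 members that rose, among them H2-T22 (1.85), Psmb10 (1.59), H2-Q4 (1.41) and H2-T10 (1.41). Tnfsf10, Daxx (2.96), Casp4 (1.63) and Casp1 (1.52) were the 4 cell death genes that rose. Usp18 (3.18), Stat2 (2.15) and Socs1 (1.5) rose, while Irf9 (0.97), Irf1 (0.30) and Jak2 (-0.06) did not pass. Irf9 reached 1.01 with median centring or cyclic loess. Tlr3, Il15 (2.10) and Il6 (1.0) rose among the inflammation genes, Il6 only just, and Il6 was at 0.98 with quantile normalization. Rhag (1.45) and Lmo2 (1.12) rose again. The 7 named genes that fell were the kinase gene Mapk8 (-1.14), Kazn (-1.08), Fgf23 (-1.05), Akap13 (-1.04), Plaur (-1.03), Pip4k2b (-1.02) and Klf9 (-1.01). Mapk8 was at -0.80 with values below the floor set to the floor. With median centring Plaur (-0.99), Pip4k2b (-0.98) and Klf9 (-0.97) missed the rule.

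Outside the interferon-linked groups few fixed lists moved in either line. Chaperones of the endoplasmic reticulum (26 measured), proliferation (29), granulocyte maturation (27), megakaryocyte (19), macrophage and dendritic cell (22), lymphoid (19), cholesterol synthesis (19), glycolysis and hypoxia (25), ribosomal protein (26), oxidative phosphorylation (26) and interferon genes themselves (19) had 0 members that passed in any comparison. Mast cell and basophil genes (23 measured) had 0 members that passed after interferon. Proliferation genes had a median of -0.12 in Calr del52 cells and -0.02 in Jak2 V617F cells. In Calr del52 cells the largest moves in that list were in Rrm2 (-0.52) and Cdk2 (-0.48).

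The responses of the lines shared most of their genes. Of the probe sets that rose, 239 rose in both, against 7.66 for independent lists among the 11186 probe sets that could pass in both. These responses share no array. Plaur was the 1 probe set that fell in both, against 0.02 for independent lists. Of the 239 shared probe sets, 173 had a smaller and 64 a larger response in Jak2 V617F cells. Their median response was 2.13 (4.38-fold) in Calr del52 cells and 1.69 (3.23-fold) in Jak2 V617F cells.

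**Figure D1:**
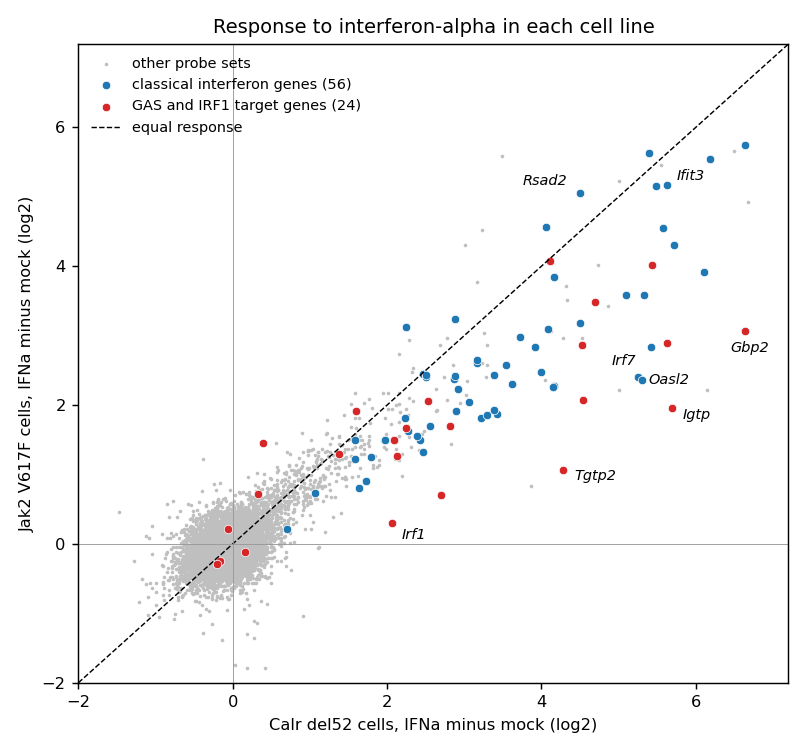
Each point is a probe set at or above the floor of 7.45 on at least 1 array, with the log2 difference between interferon and mock in Calr del52 cells on the x axis and in Jak2 V617F cells on the y axis. Most classical interferon genes (blue) and GAS and IRF1 targets (red) lie below the dashed line of equal response, with Igtp at 5.69 and 1.96, Gbp2 at 6.64 and 3.07 and Irf1 at 2.07 and 0.30, while Rsad2 (4.50 and 5.06) lies above it.

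The difference in response, Jak2 V617F minus Calr del52, addresses that question directly. By the 2-fold rule 24 probe sets had a larger and 63 a smaller response in Jak2 V617F cells. By this measure, the change from mock, smaller responses were more numerous on these arrays, opposite to the direction in the title. The line difference in level of classical interferon genes had a median of 0.78 in mock-treated cells and 0.03 after interferon. Of the 63 probe sets, 47 were interferon-induced in Calr del52 cells. Both of these comparisons use the 2 Calr del52 arrays, so part of this overlap may come from them. With a 1.5-fold rule the counts were 258 and 262. The smallest responses relative to Calr del52 cells were those of Igtp (-3.73), Gbp2 (-3.57), Tgtp2 (-3.21), Rtp4 (-2.94), Oasl2 (-2.84), Iigp1 (-2.74), Irf7 (-2.59), Irgm2 (-2.47), Ifit1 (-2.19) and Irgm1 (-1.99). Of these, all but Tgtp2, Oasl2 and Irgm1 were below the floor in mock-treated Calr del52 cells. With such values set to the floor the differences were -2.76 for Igtp, -1.82 for Gbp2 and -0.50 for Rtp4. Irf1 (-1.77) and Usp18 (-1.32) also passed, and so did Jak2 (-1.16). The Jak2 signal was already at 13.21 in mock-treated Jak2 V617F cells, against 10.74 in Calr del52 cells, possibly from a construct. Its value is therefore hard to read as a response. Stat2 (-0.87), Socs1 (-0.59) and Irf9 (-0.48) did not pass. Among classical interferon genes 20 of 59 had a smaller response and 0 a larger one, with a median of -0.83. Among GAS and IRF1 targets 11 of 28 were smaller, with a median of -0.52. The 1 larger value there, of Cxcl11 (1.06), rests on signals below the floor and was 0.07 when these were set to it. With that setting 16 classical genes had a smaller and 1, Ifi204 (1.75), a larger response, and the medians were -0.52 and -0.28. Without that setting, the medians of -0.83 and -0.52 lay below all 10000 random lists. The medians with it were not ranked. The gap depended on brightness. Of the 73 members of these lists induced in Calr del52 cells, the median difference in response was -0.89. It was -0.08 in the 11 members with an interferon-treated signal below 11 on both arrays and -0.95 in the 54 at or above 11 on both. With values below the floor set to the floor, these medians were 0.25 and -0.86, and that of all 73 members was -0.69.

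A larger response in Jak2 V617F cells was seen for Ifi211 (2.09), an interferon-induced DNA sensor family member, which rose by 3.49 in Calr del52 cells and by 5.58 in Jak2 V617F cells. Mpeg1, which encodes a pore-forming protein of phagocytes, rose by 3.01 and 4.30. Both genes were below the floor in both mock-treated samples. The interferon-treated arrays differed by 1.52 for Ifi211 and by 0.58, short of the rule, for Mpeg1, so the larger response of Mpeg1 (1.29) rests on signals below the floor. The other named genes with a larger value were Csrnp1 (1.61), Tigit (1.42), Mpdu1 (1.40), Got1 (1.31), Galnt6 (1.24), Rin1 (1.22), Itgae (1.17) and Tmem150a (1.16). None of these 8 is in the interferon lists. Csrnp1 rose by 1.23 in Jak2 V617F cells, and the values of Got1, Galnt6 and Itgae include their fall in Calr del52 cells. With values below the floor set to the floor, Rin1 (0.21), Itgae (0.15) and Tmem150a (0.12) lost the call.

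In mock-treated cells the lines already differed in interferon-linked genes. Jak2 V617F cells were at least 2-fold higher for 65 probe sets and lower for 14, and a 1.5-fold rule gave 160 and 132. The largest named differences were Gbp2 (3.88), Igtp (3.72), Rtp4 (3.56), Iigp1 (3.40), Tgtp2 (3.30), Oasl2 (2.87), Irf7 (2.47), Jak2 (2.47), Irgm2 (2.41) and Gbp4 (2.27). All but Tgtp2, Oasl2 and Jak2 were below the floor in Calr del52 cells. With such values set to the floor, Gbp2 differed by 2.13, Igtp by 2.75, Rtp4 by 1.12 and Iigp1 by 1.98, so the order is uncertain. Of the 65 probe sets, 55 were among those that interferon raised in Calr del52 cells, against 1.77 for independent lists. Both comparisons use the mock-treated Calr del52 array, so part of that excess may come from it. Simulated unchanged arrays with this sharing gave an overlap of 0 in 100 draws, because almost nothing passes the 2-fold rule there, so they do not measure what the shared array adds. None of the 14 lower probe sets was interferon-induced in Calr del52 cells. Independent lists of this size would share almost none either, and the shared array works against such an overlap, so this count says little. Classical interferon genes were higher for 20 of 59 members, with a median of 0.78 and Zbp1 at 2.15, and GAS and IRF1 targets for 11 of 28, with a median of 0.66. Irf1 (1.98) and Usp18 (1.43) were higher, and Stat2 (0.89), Socs1 (0.81) and Irf9 (0.59) did not pass. The class I presentation median was 0.32, above all random lists, with 0 of 25 members past the rule.

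Other fixed lists also held members that differed between the mock-treated lines. Among 27 STAT5 targets, of which 6 are also in another list, 3 were higher in Jak2 V617F cells, the cytokine Osm (1.29), the feedback inhibitor Cish (1.12) and Gadd45g (1.0), and the list median was 0.17, above all random lists. NF-kB and inflammation genes (0.18), cell death genes (0.12) and cholesterol synthesis genes (0.12) lay above 9989, 9937 and 9991 of the 10000 random lists, so a median of this size does not set the STAT5 targets apart. Gadd45g was at 0.95 with median centring and at 0.99 with values below the floor set to the floor. Osm was also raised by interferon in Calr del52 cells (1.20), and Cish, which is also in the signalling list, was not (-0.43). The named lower genes were Far2 (-2.27), the mast cell carboxypeptidase Cpa3 (-1.99), Tigit (-1.47), the melanocortin receptor gene Mc5r (-1.21), Rbm47 (-1.19), Klrb1f (-1.19), the actin-severing Scin (-1.19), Fam160a1 (-1.18), Lgr4 (-1.12) and Pik3c2g (-1.06). Rbm47 was at -0.38 with values below the floor set to the floor, and Pik3c2g was at -0.999 with cyclic loess, just short of the rule. Cpa3 was the 1 member of 23 mast cell and basophil genes that passed, and the list median was -0.06. Il6 was lower (-1.02), but at -0.96 with cyclic loess. Casp4 (1.15), which interferon raised in both lines, was the 1 cell death gene that was higher.

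**Figure D2:**
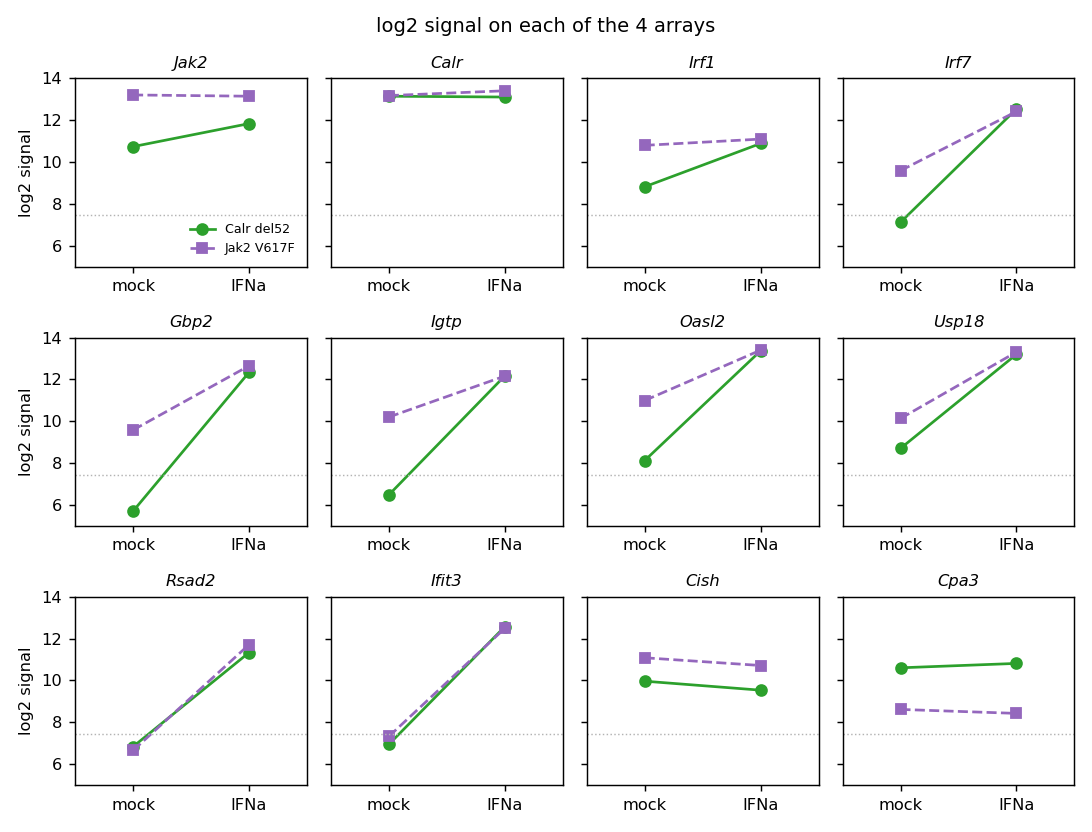
The log2 signal of 12 genes is shown on each of the 4 arrays, with treatment on the x axis, circles for Calr del52 cells, squares for Jak2 V617F cells and a dotted line at the floor of 7.45. Gbp2, Igtp, Oasl2, Irf7 and Irf1 start higher in Jak2 V617F cells and end at levels that differ by at most 0.31, Rsad2 and Ifit3 start below the floor in both lines, and Jak2, Cish and Cpa3 differ between the lines in both treatments.

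After interferon fewer differences between the lines passed the rule. Of all probe sets, 19 were at least 2-fold higher and 16 lower in Jak2 V617F cells. The 239 shared probe sets had a median line difference of 0.42 in mock-treated cells and 0.04 after interferon. Irf7 (-0.12), Stat2 (0.02), Usp18 (0.11), Irf9 (0.11), Irf1 (0.21) and Socs1 (0.22) did not pass. Among classical interferon genes 1 of 59 was higher, Ifi204 (1.76), with a list median of 0.03. Among GAS and IRF1 targets 1 of 28 was higher, Cxcl11 (1.11), which lost the call at 0.07 with values below the floor set to the floor. The list median of 0.22 lay above all random lists, where proliferation genes (0.11) and cholesterol synthesis genes (0.13) lay above 9998 and 9994 of 10000, with Il18bp at 0.78, Iigp1 at 0.66 and Cxcl10 at 0.65. The 54 induced members of both lists at or above 11 on both arrays had a median of 0, and 10 of the 11 below 11 were higher in Jak2 V617F cells, with a median of 0.27. Over the 239 shared probe sets no steady trend of this line difference with level was seen, with medians of 0.09 at levels from 7 to 9, 0.28 from 9 to 10, 0.05 from 10 to 11, 0.04 from 11 to 12 and 0.02 above 12. The mock difference of these probe sets did rise with level, from 0.16 at 7 to 9 to 0.87 above 12. Their difference in response was -0.04 at 7 to 9 and -0.86 above 12. The other named higher genes were Cdh17 (1.71), Lilrb4a (1.64), Ifi211 (1.52), Serpina3f (1.45), Slfn2 (1.41), Gem (1.36), Csrnp1 (1.32), Jak2 (1.31) and Cish (1.18). Cdh17 (0.83) and Lilrb4a (0.02) lost the call with values below the floor set to the floor. The inflammatory cytokine Tnf was higher by 1.08. Lower genes were Cpa3 (-2.39), Far2 (-2.10), Akap13 (-1.36), Lgr4 (-1.21), Emp1 (-1.12), Slc37a2 (-1.10), Fam160a1 (-1.05), Gria3 (-1.05), Scin (-1.05) and Mc5r (-1.05), of which Lgr4 (-0.83) and Slc37a2 (-0.16) lost the call with that setting. Of the 19 higher probe sets, 9 were interferon-induced in Jak2 V617F cells, against 0.47 for independent lists, and these comparisons share the interferon-treated Jak2 V617F array.

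**Figure D3:**
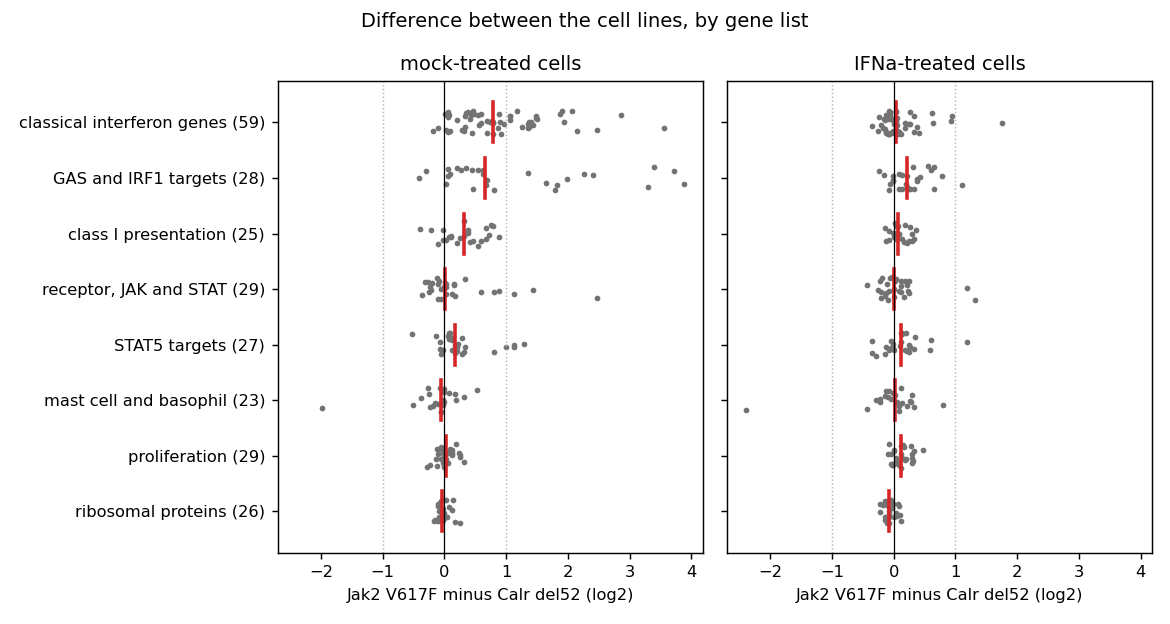
Each point is a measured member of a fixed gene list, with the log2 difference Jak2 V617F minus Calr del52 on the x axis for mock-treated (left) and interferon-treated cells (right), red bars at the list medians, dotted lines at a difference of 1 in either direction and members counted in parentheses. The medians of classical interferon genes and of GAS and IRF1 targets are 0.78 and 0.66 in mock-treated cells and 0.03 and 0.22 after interferon, and Cpa3 lies at -1.99 and -2.39 among mast cell and basophil genes.

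A smaller set of genes separated the lines in both treatments. In Jak2 V617F cells 12 probe sets were higher in both, against 0.11 for independent lists, and 7 were lower in both. These comparisons share no array. The 8 named higher genes were Jak2, Lilrb4a, Cdh17, Apol9a (1.49 in mock-treated cells and 1.07 after interferon, chosen after its values were seen), Serpina3f, Gem, Slfn2 and Cish. The 7 lower genes were Far2, Cpa3, Mc5r, Scin, Fam160a1, Lgr4 and Gria3 (-1.06 and -1.05). With values below the floor set to the floor, 8 probe sets were higher and 6 lower in both. Cdh17 and Lilrb4a, which lay below the floor in both Calr del52 samples, then lost the call in both treatments, and Lgr4 after interferon. In the additive limma model, 0 probe sets passed for the line effect in either direction, with 900 at an unadjusted p under 0.05. The smallest limma adjusted p was 0.346, shared by genes that included Far2 (-2.19, SE 0.0939), Cpa3 (-2.19, SE 0.136), Lilrb4a (1.70, SE 0.0871), Cdh17 (1.61, SE 0.0996), Serpina3f (1.42, SE 0.0835) and Gem (1.36, SE 0.0819). Quantile normalization gave 12 higher and 8 lower probe sets for this effect, and cyclic loess gave 15 and 9.

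For the interferon effect over both lines, the same limma model called 133 probe sets higher and 1 lower, and 2012 had an unadjusted p under 0.05. The smallest adjusted p, 0.0149 in limma, belonged to Tlr3 (5.51, SE 0.0854), Ifit1bl2 (5.51, SE 0.104) and Cxcl10 (4.09, SE 0.0826), each higher in both lines. Ifit3b (5.32, SE 0.123) followed with a limma adjusted p of 0.0190. Ifit3 (5.40), Phf11d (4.00), Gm7609 (3.15), Mx1 (5.87), the death-domain-associated gene Daxx (2.87) and Parp11 (2.46) had a limma adjusted p of 0.0276. Plaur was the 1 gene that fell (-1.07, SE 0.0840, limma adjusted p = 0.0478). Fgf23 had an effect of -1.01 at a limma adjusted p of 0.0534, and the next values were those of Etfbkmt (-0.85), Peg12 (-0.78), Slc39a14 (-0.74), Polr3g (-0.82), Kiss1r (-0.76), Pwp2 (-0.68), Dus4l (-0.71) and Pus7 (-0.72). The split of calls depended on the normalization, with 535 higher and 151 lower after quantile normalization and 632 and 106 after cyclic loess. Without the mock-treated Calr del52 array, or without either interferon-treated array, 0 probe sets were called higher, and without the mock-treated Jak2 V617F array 72 were.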

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

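The minimum move of 0.2 used in this part was chosen after the responses were seen. Among the named genes, 8 had log2 responses to interferon of at least 0.2 in opposite directions in the lines and a difference between these responses of at least 1, with 1 array behind each level. The difference between the lines was not tested for any of them, and none is a member of the fixed interferon lists. Several of the single responses lie close to the spread of dim probe sets, which ran from -0.54 to 0.50 in Calr del52 cells.

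Akap13, a Rho guanine nucleotide exchange factor and kinase anchor, was at 8.56 and 9.47 (mock and interferon) in Calr del52 cells and at 9.15 and 8.11 in Jak2 V617F cells, a difference in response of -1.95. Mapk8, which encodes the stress kinase JNK1, moved by 0.31 and -1.14, a difference of -1.45. Csrnp1 moved by -0.38 in Calr del52 cells and 1.23 in Jak2 V617F cells, a difference of 1.61. The inhibitory receptor gene Tigit moved by -0.85 and 0.57, a difference of 1.42. For Mpdu1 the responses were -0.78 and 0.62, and the difference was 1.40. Got1, the cytosolic aspartate aminotransferase, moved by -1.05 and 0.26, a difference of 1.31. Rin1 (-0.83 and 0.39) differed by 1.22 and Tmem150a (-0.40 and 0.76) by 1.16, but 5 of these 8 signals lay below the floor. With values below the floor set to the floor these differences were 0.21 and 0.12, and Rin1, Tmem150a and Csrnp1 (-0.12 in Calr del52 cells) no longer moved by 0.2 in both lines.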

How the results depend on the processing

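The direction of the named results mostly held. Over quantile normalization, median centring and cyclic loess, 1460 values of named genes stayed on their side of the 2-fold rule, 17 dropped below it and 2 rose past it, and 0 of those past the rule changed sign; the largest shift was 0.11. List medians stayed within 0.2 in 493 cases and moved further in 14, and 3 that lay outside the central 95% of random lists changed sign. All 3 sign changes and 10 of the moves came from keeping only members at or above the floor, 4 moves from the added floor setting below, and the largest shift under a normalization was 0.08. Medians inside the central range, at most 0.16 in size, changed sign in 46 cases. The 3 sign changes were: megakaryocyte genes after interferon between lines (-0.02), mast cell and basophil genes in the difference in response (-0.045, from 0.15) and lymphoid genes after interferon between lines (0.02), where fewer members enter by construction.

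Counts by the size rule moved with the rule itself. At 1.5-fold, 517 probe sets were higher and 213 lower after interferon in Calr del52 cells, 534 and 152 in Jak2 V617F cells, 258 and 262 for the difference in response, 160 and 132 between mock-treated lines, and 90 and 97 between interferon-treated lines, with 421 higher in both lines. At 4-fold the counts were 131 and 0, 94 and 0, 1 and 13, 18 and 1, and 1 and 2 in the same order, with 88 shared. Counted over all probe sets that met the floor, the excess of smaller over larger responses in Jak2 V617F cells is thus absent at 1.5-fold. A 1.5-fold difference lies inside the range of dim probe sets for this comparison, from -0.74 to 0.63. Without a size rule, 52 of 59 classical interferon genes had a smaller and 6 a larger response. Of the 239 probe sets that rose in both lines, 173 had a smaller and 64 a larger response. A floor at the 75th percentile left 6 lower probe sets after interferon in each line, 8 with a larger response, 30 higher and 9 lower between mock-treated lines, and 11 and 6 between interferon-treated lines. Without a floor, 54 had a larger and 111 a smaller response. Cyclic loess left 9 lower in Calr del52 cells. Setting values below the floor to the floor, an alternative added after seeing the data, left 10 lower in Jak2 V617F cells and 9 lower between interferon-treated lines. Of 493 values of named genes, 15 dropped below the 2-fold rule under it. It moved the median difference in response to -0.52 for classical genes and -0.28 for GAS and IRF1 targets. Apart from these, counts by the size rule stayed within 1.5 times under the other settings.

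The limma calls for the interferon effect were the least stable. Against 133 higher and 1 lower, limma called 49 and 0 without a floor, 220 and 2 with median centring, 535 and 151 with quantile normalization, 632 and 106 with cyclic loess, 439 and 50 without the block, and 237 and 3 with a variance trend; the 75th percentile floor gave 2 lower. Leaving out 1 array, which also removes the block, gave 0 to 72 higher and 0 lower; the group left with 1 array is assumed to vary like the other. For the line effect quantile normalization gave 12 and 8 calls and cyclic loess 15 and 9, against 0 in each other setting. The prior degrees of freedom were 2.43 for the deposited values, 6.50 after cyclic loess and 5.79 after quantile normalization; the cause of these changes was not tested. The gap in response of induced members fell to -0.08 below a signal of 11, an alternative chosen after seeing the data. The median difference there was 0.25 with values below the floor set to the floor. The limma fit with line as the block compares interferon and mock within each line, and no other pairing of arrays exists here. Arrays set no depth, and differences of dim probe sets are limited by signal over background.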

Other observations

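Gene families were picked out after the values were seen, and each count below uses the 2-fold rule. Of 9 measured Schlafen genes, 8 rose after interferon in Calr del52 cells and 7 in Jak2 V617F cells, with Slfn1 at 1.45 and 1.36 and Slfn5 at 5.58 and 4.55. All 4 measured Phf11 genes rose in both lines, with medians of 3.67 and 3.74. Among 11 PARP genes, 4 rose in Calr del52 cells and 5 in Jak2 V617F cells, with Parp14 at 3.91 and 2.83 and Parp9 at 3.22 and 1.81. Among 61 Trim genes, 8 and 9 rose, including Trim30d (4.73 and 4.01) and Trim21 (3.66 and 2.31). Quantile normalization, median centring and cyclic loess each gave 9 Trim genes in Calr del52 cells and left the Schlafen, Phf11 and PARP counts at these values. With values below the floor set to the floor, 7 and 6 Schlafen genes rose. Toll-like receptors and chemokines moved singly. Of 12 Toll-like receptors 1 rose in each line, Tlr3. Of 36 chemokines Cxcl10 alone rose in Calr del52 cells (4.11), and Cxcl10 (4.07) and Cxcl11 (1.45) rose in Jak2 V617F cells, with the same counts under each of those normalizations. Cxcl11 lost this call at 0.07 with values below the floor set to the floor.

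The PYHIN family includes cytosolic DNA sensors. Of 9 measured members, 4 rose in Calr del52 cells and 5 in Jak2 V617F cells, with a median difference in response of 0.59. Ifi211 (3.49 and 5.58) had a difference in response of 2.09, which passed the rule. Ifi204 (2.25 and 3.13), Ifi207 (2.28 and 2.93) and Mndal (2.15 and 2.74) had differences of 0.88, 0.65 and 0.59, which did not pass, beside a central 95% of dim probe sets from -0.74 to 0.63. Several mock signals of these genes lay below the floor. With such values set to the floor, Ifi204 (1.75) and Ifi211 (1.52) both passed, Ifi207 (0.81) did not, and 3 and 4 members rose in the 2 lines. These 4 genes had interferon-treated signals below 11 on both arrays, where the induced members of the fixed interferon lists had a median difference in response of -0.08. With values below the floor set to the floor that median was 0.25, and Ifi204 is itself among those members. After interferon, Ifi204 and Ifi211 were higher in Jak2 V617F cells by 1.76 and 1.52, while in mock-treated cells the differences were 0.88 and -0.57. Cyclic loess gave 5 members that rose in Calr del52 cells, and 2 were higher after interferon under each normalization. These genes lie in a family of close paralogs, and probes shared between members cannot be separated here.

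All tests in the next 2 paragraphs were chosen after the pattern was seen. The first pattern is that interferon-induced genes were higher in mock-treated Jak2 V617F cells and responded less there. If the lines did not otherwise differ, mixing of interferon-treated RNA into that sample would place every induced gene at the level of one common share. Of 64 strongly induced list members, 15 were 2-fold or more off that level, 10 below and 5 above, with implied shares from -0.54% to 92.1%. With values below the floor set to the floor, 12 were that far off, 8 below and 4 above. The shares were computed from the Calr del52 arrays, taking unmixed Jak2 V617F cells to equal mock-treated Calr del52 cells. Mixing on top of another line difference is therefore not excluded. Among quantile normalization, median centring and cyclic loess, the median difference in response of the 73 induced members was at weakest -0.87. These were applied to the deposited values, and the largest shift of a list median under them was 0.08. They therefore cannot exclude an effect of the processing that gave the deposited values. An array ceiling cannot produce the mock difference, a median of 0.88 with 71 of 73 members higher. With values below the floor set to the floor, the median was 0.74 and 63 members were higher. Of the 73 members, 30 lay below the floor in mock-treated Calr del52 cells. The 73 members were chosen by their rise in Calr del52 cells, which uses that same array, so part of the mock difference may come from it. The split at a signal of 11 cannot decide whether a ceiling made the response smaller. The gap was -0.08 in the 11 members whose interferon-treated signals stayed below 11, or 0.25 with values below the floor set to the floor. Those members also had a smaller mock difference, 0.47. Over the 239 shared probe sets, the mock difference rose with level, from 0.16 at levels from 7 to 9 to 0.87 above 12. Their line difference after interferon was 0.05 from 10 to 11 and 0.02 above 12. The order of the responses thus stays open, and the Jak2 V617F genotype stays open as untested, since each genotype is 1 line with 1 mock-treated array.

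The second pattern is a difference between the interferon lists among their strongly induced members. Among members that rose at least 4-fold in Calr del52 cells, 16 GAS and IRF1 targets had a median mock difference of 1.81 and 48 classical genes 0.91, whereas over all measured members the medians were 0.66 and 0.78, since more of the GAS and IRF1 list was not induced. As a share of the response of Calr del52 cells these mock differences had medians of 0.49 and 0.27, a gap of 0.23, and the gap was 0.18 among the 73 members that rose at least 2-fold. After a linear correction for baseline level and response size 0.21 remained, a gap that 3 of 10000 random splits of these genes matched. Genes of a list are not independent, however. A linear correction need not remove a dependence of another shape, and both parts of the share use the mock-treated Calr del52 array. Baseline level and response size are therefore not excluded. Interferon made by the unstimulated cells stays open, because 0 of 19 measured interferon genes were 2-fold higher but 14 of them lay below the floor on both mock-treated arrays, and activity of STAT1 homodimers or IRF1 without added interferon stays open as untested.

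Smaller responses remain among the probe sets that did not pass the rule. Among 11369 probe sets above the floor that did not pass in either response, the SD of the averaged log2 difference was 0.208 for treatment, 0.170 for line and 0.131 for the crossed contrast that neither factor explains. Differences of at least 0.5 were seen for 379, 111 and 21 of these probe sets. The selection by response limits the treatment and crossed contrasts but not the line contrast, so these values are not on a like footing. Jak2, which rose by 1.10 after interferon in Calr del52 cells, moved by -0.06 in Jak2 V617F cells, where it started at 13.21.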
